A study of Escherichia coli str. K-12 substr. MG1655 with 12 samples.

How the data were processed

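Fur was measured in 4 libraries and RpoB in 8, in 6 groups of 2 taken from the sample titles: Fur with iron, Fur with DPD, and RpoB with iron or DPD, each without or with rifampicin. The deposited files give coverage, a whole-number signal per base and strand that is not scaled to depth. Reads were aligned with Bowtie 1.0.0 to ASM584v2, per the submitters' processing notes. No filter on reads, duplicates or mapping quality, and no pooling of replicates, is given in the sources used here.

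Tests on the values showed that 8 of the deposited files are the exact sum of reads of 31 bases, so that read numbers and read ends could be recovered from the coverage. The 4 RpoB files with DPD, with or without rifampicin, are not. Isolated reads were counted only up to 31 bases and above a minimum length, so longer and very short reads would not be seen. Among those counted in these 4 files 69.1% to 70.7% had 31 bases, and the mean was 30.6. Their read numbers were estimated as coverage divided by that mean, and depend on this range of lengths. Total coverage ran from 21298829 bases in the second Fur library with iron to 186272397 in the first RpoB library with iron and rifampicin.

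The files end at position 4639675, and 4 of the 4651 genes in the table of ASM584v2 genes end beyond it. The files thus do not share the build of that table, although the processing notes name ASM584v2 as the reference. No coordinates were taken from the table and no gene was named. The fallback fixed before the data were examined, 1 kb bins in place of genes and promoters, was used: 4639 bins and 46396 tiles of 100 bases. Tests planned on annotated features were not run, namely known Fur promoters, gene groups and the promoter to gene ratio. Ribosomal RNA genes could not be left out of the totals for the same reason.

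Fur regions were defined without regard to condition, as tiles whose mean over the 4 Fur libraries reached 5 times the median tile and that reached 3 times the median in at least 2 libraries, merged when at most 100 bases apart. This gave 32 regions from 90 tiles. Enrichment is the signal per base of a region divided by the library's median tile.

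Bins and regions were compared with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean, on log2 of the signal plus a pseudocount of 0.5 of the median feature signal. The signal was first divided by the library mean and by a trimmed-mean factor computed over 1 kb bins (30% of ratios and 5% of levels trimmed). Fold changes on this scale, and with them the counts of changes of 2-fold or more, understate changes of features that are low in either group. Strong Fur regions are among them: at 4603401 to 4604100 a 56.2-fold difference of means gave a log2 change of -4.26. The order of log2 changes can therefore differ from that of the ratios of means. The pseudocount was 0.200 for RpoB bins and 2.46 for Fur regions. All 8 RpoB libraries entered 1 fit of the bins, with 4 residual and 49.0 prior degrees of freedom. The Fur libraries entered separate fits of the regions and of the 1 kb bins, each with 2 residual degrees of freedom. RpoB windows around the 32 Fur regions had a fit of their own, with its own pseudocount and variance trend. Standard errors in that fit ran from 0.0085 to 0.079. For the Fur regions the prior degrees of freedom were infinite. Their tests thus used the variance trend over the 32 regions and not the spread of each region. The median standard error of a log2 change was 0.048 for RpoB bins and 0.058 for Fur regions. A change was called at a Benjamini-Hochberg adjusted p under 0.05. The plan had given whole read counts a count model and coverage the limma test, and the latter applied. A filter of 10 read equivalents in 2 libraries removed no bin.

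On simulated data with 200 changed bins among 4639, the Fur step recovered 100% of changes of 1.5, 2, 4 and 8-fold with 3 false calls. The RpoB step recovered 88% of 1.5-fold and 100% of larger changes with 8 false calls. Noise in these simulations was drawn with an assumed spread between replicates, so the shares hold for that spread only.

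Bins to be named were, in each contrast, the 10 highest and 10 lowest log2 changes past the threshold whose groups do not overlap and whose mean signal is at or above the median, 1 for each run of neighbouring bins. For Fur regions they were the 10 highest enrichments and the 10 largest changes in each direction. This rule, the groups, the region definition, the contrasts and most alternatives were fixed before the data were examined. Region windows of 1 kb, the read filter, the trimming in place of a packaged factor, the share of the highest tile, the 2-fold counts near Fur regions and their circular shifts (in place of Fisher's exact test, which takes bins as independent), the distance classes, the read end positions, bins of 500 bases, a pseudocount of 0.1 of the median and thinning to 40 reads were chosen after seeing the data. The windows named around Fur regions and the Fur regions named for their RpoB signal were chosen for their values.

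Sets of bins were tested with camera (preset correlation of 0.01, and estimated) and fry. Exact permutation tests, circular shifts of changed bins along the genome, and 100000 permutations for correlations across regions were run in Python 3.11.15 with SciPy 1.17.1, numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9. Alternatives covered the scaling, the variance trend, the pseudocount, the filter, the region threshold, the bin size, the libraries in the fit, a block on the replicate number and leaving out each library in turn.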

Results

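Binding of the iron-responsive regulator Fur and of RNA polymerase was mapped by ChIP-exo in Escherichia coli K-12 MG1655 grown aerobically at 37 °C in M9 medium with 0.2% glucose. ChIP-exo is chromatin immunoprecipitation followed by exonuclease trimming, so that read ends lie close to the edges of the bound protein. Fur, a repressor that binds DNA when loaded with iron, was precipitated through a myc tag in a tagged strain. RNA polymerase was precipitated through its β subunit, RpoB, in wild-type cells. Cells received either 0.1 mM FeCl2 from the start of culture or 0.2 mM of the iron chelator DPD for 2 h, and some RpoB cultures also received rifampicin for 20 min. Rifampicin blocks RNA polymerase from leaving promoters, and the design names it as the means of seeing static polymerase. The 12 libraries form 6 groups of 2, which the series design calls biological duplicates.

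The Fur libraries held 2618481 and 687059 reads with iron and 3262969 and 2579866 with DPD. The RpoB libraries held 5696200 and 5549925 reads with iron, and 6008787 and 5754923 with iron and rifampicin. An estimated 4527738 and 4475268 were present with DPD, and 4858558 and 5498095 with DPD and rifampicin. Libraries of a group differed beyond counting noise. Chi-square per degree of freedom over 100-base tiles ran from 1.02 for Fur with iron (p = 0.00804, a test over tiles) to 1.39 for RpoB with DPD. Over the 1 kb bins used in the tests it reached 1.57 for RpoB with iron and rifampicin, 1.68 with DPD and 1.84 with DPD and rifampicin. Each pair was kept as 2 libraries. P-values measure the spread within such pairs, pooled mostly across bins and, for Fur regions, wholly across regions. That spread may be smaller than the spread between independent cultures. Positions below are those of the deposited files, counted from 1 on the E. coli chromosome. No gene names are attached, because the files and the gene table used here differ in build.

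The comparison of Fur with iron and with DPD asked how binding depends on available iron. Averaged over the 4 Fur libraries, signal reached 5 times the median tile in 32 regions, and 29 of them fell with DPD. Signal in these 29 regions ranged from 8.17 to 73.6 times the library median with iron (median of the regions 25.96) and from 0.870 to 2.27 with DPD (median 1.26). Region means with iron were 3.60 to 56.2 times those with DPD. The region at 4603401 to 4604100 had the highest Fur signal, 73.6 ± 1.54 with iron against 1.31 ± 0.037 with DPD (SD, n = 2). The next highest lay at 1160501 to 1161300, where the signal was 69.1 ± 1.44 with iron and 1.32 ± 0.025 with DPD, and at 2244701 to 2245300, where it was 67.8 ± 0.573 and 1.26 ± 0.022.

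Log2 changes, shrunk by the pseudocount of 2.46, were -4.26 at 4603401 to 4604100, -4.16 at 1160501 to 1161300 and -4.16 at 2244701 to 2245300. They were -3.95 at 3578701 to 3579400, -3.83 at 623701 to 624400 and -3.60 at 611601 to 612200. The regions at 1521201 to 1521300 and 1577301 to 1577400 fell by 3.59 and 3.52. The smallest of the 29 falls was at 1984901 to 1985000, where Fur went from 8.17 ± 0.330 to 2.27 ± 0.025. The 3 remaining regions had low Fur signal in every library. At 3580801 to 3580900 the signal rose from 3.75 ± 0.192 to 6.59 ± 0.571, a log2 change of 0.53 (SE 0.091). At 255801 to 255900 it was 5.18 ± 0.525 with iron and 5.45 ± 0.093 with DPD, and at 3595801 to 3595900 it was 5.13 ± 1.17 and 5.26 ± 0.080, without a call. RpoB signal with iron and rifampicin stood at 10.7 ± 0.896, 30.8 ± 1.57 and 24.8 ± 0.194 times the median in these 3 regions. Without rifampicin, which no Fur library received, it was 1.21 ± 0.0046, 5.97 ± 0.089 and 6.70 ± 0.856 with iron. Regions that lost Fur ranged from 0.549 to 53.1 with iron and rifampicin, so high RpoB signal did not set these 3 apart. The rise at 3580801 to 3580900 was not called when the first DPD library was left out, and without either iron library there were 2 rises.

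**Figure D1:**
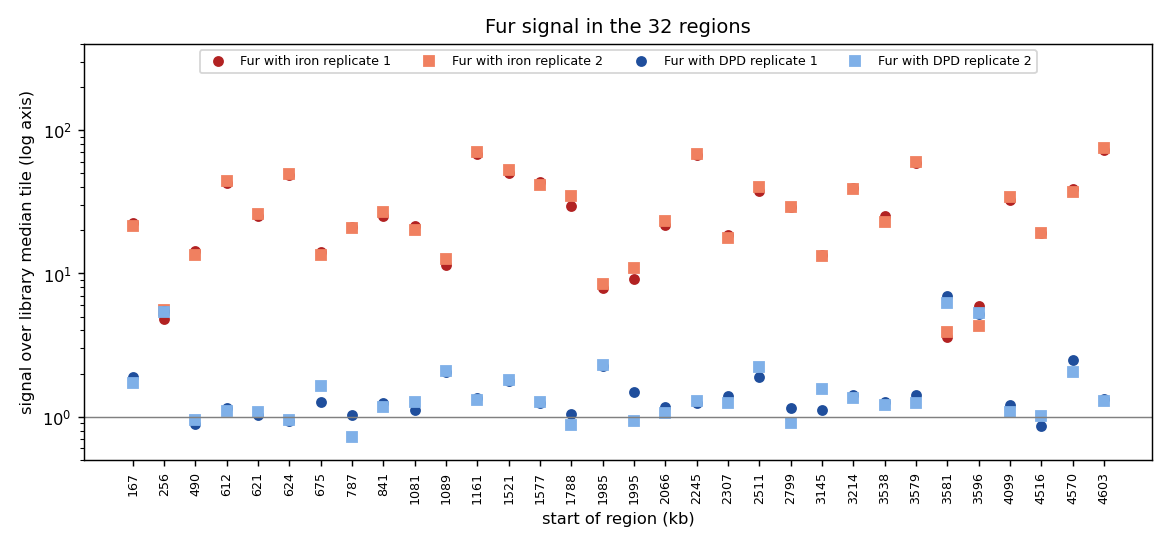
Fur signal in each of the 32 regions (x axis, start in kb) relative to the library's median 100-base tile (y axis, log scale), with 1 point per library. In 29 regions both iron libraries lie above both DPD libraries, with means of 8.17 to 73.6 against 0.870 to 2.27.

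The test was limma with Benjamini-Hochberg adjustment over the 32 regions, scaled on the whole genome, and the median log2 change was -2.82. This median depends on the pseudocount and the region threshold. It ran from -1.96 to -3.63 with 1 library left out, and was -3.86 with a pseudocount of 0.1 of the median signal. With regions at 3 times the median tile it was -0.36, with 15 higher and 38 lower of 74, and at 10 times it was -2.99, with 23 lower of 23 (limma). A scale set on the regions themselves centres them by construction and gave 13 higher and 12 lower. Across 1 kb bins of the genome, Fur signal was higher in 1114 and lower in 1084 of 4639 with DPD. On the log2 scale with its pseudocount of 0.467, 33 bins fell by 2-fold or more and none reached that as a rise, although means without the pseudocount did. The largest log2 rise of the named bins was at 1422001 to 1423000, from 0.785 ± 0.055 with iron to 1.68 ± 0.050 with DPD (SD, n = 2). These values are relative to the scaled library mean, and the bin lay away from the Fur regions.

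The highest read ends of both strands were compared in the Fur regions. In 27 regions with iron signal of at least 10 times the background, the highest end on the plus strand lay upstream of the highest end on the minus strand in 27 of 27 in each iron library. Median spacing was 20 bases in the first library and 26 in the second. Spacings varied widely, with quartiles of 11 and 31 bases in the first library. The highest end was picked on each strand separately, so a pair need not be the borders of 1 bound site. The spacing was identical in both libraries in 22 regions and within 2 bases in 24. The highest single read end of both iron libraries was at 4603730 on the minus strand, with 3315 and 907 reads, followed by 2244995 on the minus strand with 3213 and 902.

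The comparison of RpoB with DPD and with iron asked where RNA polymerase moved when iron was withdrawn. Polymerase signal is given here relative to the scaled mean of its library. Its largest log2 rise of the named bins was at 2799001 to 2800000, from 0.205 ± 0.017 with iron to 5.64 ± 0.154 with DPD (SD, n = 2). It rose from 0.119 ± 0.011 to 3.38 ± 0.033 at 612001 to 613000 and from 0.101 ± 0.0083 to 1.85 ± 0.0082 at 624001 to 625000. All 3 bins lie beside or on Fur regions that lost Fur. The bins at 3578001 to 3579000, 4515001 to 4516000 and 2509001 to 2510000 also belong to rising runs within 1 kb of a Fur region, with log2 changes of 2.69, 2.48 and 2.32. Rises away from Fur regions were led by 1761001 to 1762000, where the signal went from 0.279 ± 0.052 to 3.89 ± 0.066.

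The largest log2 fall of the named bins, a change of -4.82, was at 2039001 to 2040000. Polymerase went there from 16.7 ± 0.399 with iron to 0.397 ± 0.013 with DPD. Signal fell from 5.72 ± 0.239 to 0.252 ± 0.013 at 311001 to 312000 and from 10.3 ± 0.048 to 0.894 ± 0.031 at 1940001 to 1941000. At 4208001 to 4209000, within a falling run from 4205001 to 4212000, it went from 15.8 ± 0.0079 to 3.29 ± 0.041. The bin at 2066001 to 2067000 was the only one of the 10 leading falls within 1 kb of a Fur region. It fell from 4.81 ± 0.104 to 0.830 ± 0.018, although Fur in the region at 2066301 to 2066900 fell as well, by 2.73 on the log2 scale.

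Across the genome 1660 bins were higher and 1568 lower with DPD of 4639 tested by limma, 128 and 221 of them by 2-fold or more. With a pseudocount of 0.1 of the median signal, 200 rises and 307 falls reached 2-fold. The 2 groups did not overlap in 82.9% of bins, against 33.3% by chance. The balance of directions rests on the scale: the highest 1% of tiles held 30.8% ± 0.200 of the signal with iron and 19.6% ± 0.044 with DPD (SD, n = 2), and with library totals the median bin shifted by 0.22. Under that scale 3249 bins were higher and 738 lower, with 237 and 146 at 2-fold or more, so that large rises outnumbered large falls. The RpoB files with DPD also held some reads shorter than 31 bases and those with iron did not, a technical difference that goes with the iron condition in every RpoB library.

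Around the Fur regions RNA polymerase mostly rose with DPD. Windows reaching 1 kb to each side rose at 21 of the 32 regions and fell at 8, and 8 rose by 2-fold or more. Of the 29 regions that lost Fur, 21 rose and 5 fell. The largest rises were at 2798701 to 2798900 (log2 change 2.55), 611601 to 612200 (2.38), 3578701 to 3579400 (1.93) and 623701 to 624400 (1.91). Windows at 2510601 to 2510800 and 621201 to 621700 rose by 1.35 and 1.21. Falls were led by 2066301 to 2066900 (-1.47) and 4570201 to 4570300 (-0.95), while the windows at 3214301 to 3214900 and 3595801 to 3595900 fell by 0.62 and 0.70.

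**Figure D2:**
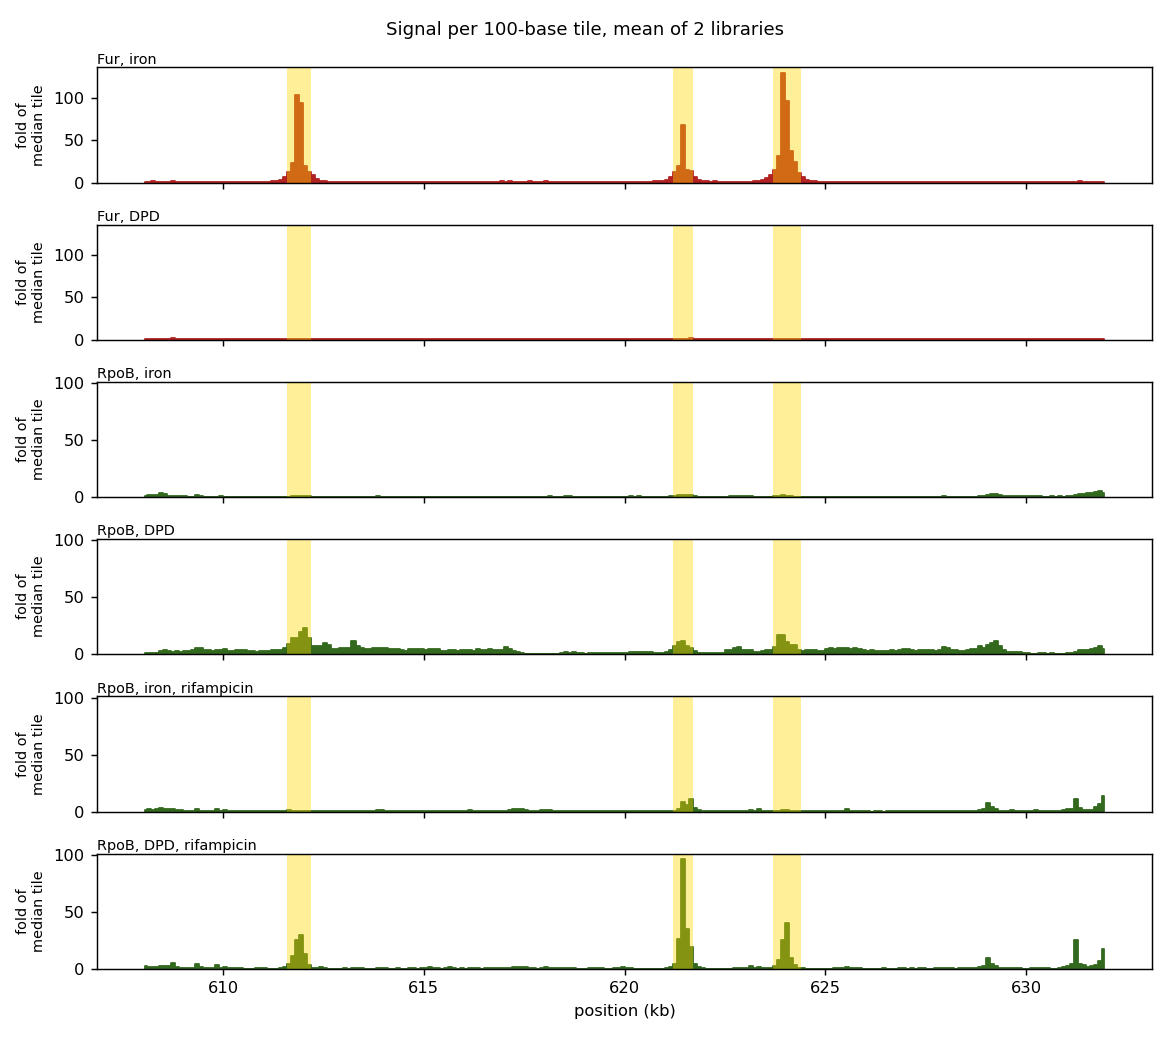
Signal per 100-base tile relative to the library median (y axis, mean of 2 libraries per group) along a stretch of the chromosome (x axis, kb) that holds 3 Fur regions, shaded. Fur means of 43.6, 25.7 and 48.99 in these regions with iron fell to between 0.943 and 1.13 with DPD, where RpoB means were 15.96, 8.47 and 10.2 against 0.638, 1.60 and 0.717 with iron.

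The median change of the 32 windows was 0.35, and with library totals it was 0.61, with 26 rises and 4 falls and a changed direction at 5 regions. Among the 99 bins within 1 kb of a Fur region, 65 rose, 26 fell and 8 were not called, with a median log2 change of 0.31 and a mean of 0.62. Adjusted over the list alone, the counts were also 65 and 26. Camera, which compares the bins with the rest of the genome, gave p = 3.67e-08 with a preset correlation of 0.01. With an estimated correlation camera gave p = 0.00152. That estimate was -0.0099, below the preset, so the larger p did not come from a stronger correlation. Fry, which allows for correlation between bins and asks only whether the bins moved on balance in 1 direction, gave p = 6.42e-11. Bins that rose by 2-fold or more lay within 1 kb of a Fur region in 35 of 128 cases, where 2.73 are given by chance. Neighbouring bins are not independent, and these 35 formed 17 runs near 19 regions. Of the 4639 circular shifts of the changed bins, which keep such runs, only the real placement gave as many (permutation test, one-sided, p = 0.000216, the smallest possible). Bins that fell by 2-fold or more were near a Fur region in 4 of 221 cases, where chance gives 4.72 (permutation p = 0.630). With library totals 38 of 237 rises and 2 of 146 falls of that size lay near a Fur region (permutation p = 0.000431 and 0.694), and 75 of the 99 bins rose and 14 fell. With the wider list of regions at 3 times the median tile, the median change of nearby bins was 0.06 and the camera call was lost (p = 0.185 with the preset correlation).

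With rifampicin the same iron comparison looked at polymerase held near its starting points. The largest log2 rise of the named bins, a change of 2.54, was at 4603001 to 4604000, on the strongest Fur region. The signal went there from 0.908 ± 0.020 with iron to 6.24 ± 0.014 with DPD (SD, n = 2). Signal rose from 0.112 ± 0.0030 to 1.42 ± 0.023 at 611001 to 612000, from 0.0763 ± 0.00089 to 1.08 ± 0.042 at 624001 to 625000 and from 0.668 ± 0.017 to 3.68 ± 0.038 at 621001 to 622000. Bins at 2244001 to 2245000, 3579001 to 3580000, 167001 to 168000, 1577001 to 1578000 and 1521001 to 1522000 rose by 1.94, 1.93, 1.81, 1.54 and 1.47. In all, 9 of the 10 leading rises were within 1 kb of a Fur region, and the exception was 808001 to 809000, which rose from 0.200 ± 0.0059 to 1.54 ± 0.046.

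Falls with rifampicin began with bins that had also fallen without it. At 2039001 to 2040000 polymerase went from 5.66 ± 0.053 to 0.430 ± 0.052, and at 1940001 to 1941000 from 7.94 ± 0.229 to 1.61 ± 0.050. Within the Fur regions themselves both directions were seen. RpoB signal over the median tile went from 8.58 ± 0.971 to 68.8 ± 3.85 at 1577301 to 1577400, from 28.3 ± 1.81 to 110.2 ± 2.86 at 1521201 to 1521300 and from 37.4 ± 1.60 to 111 ± 1.54 at 4098601 to 4098800. It went from 53.1 ± 2.45 to 18.8 ± 0.517 at 4570201 to 4570300 and from 9.86 ± 0.762 to 5.70 ± 0.297 at 3144501 to 3144600. Of the 10 leading falls across bins, 2 lay within 1 kb of a Fur region. Mean RpoB signal was higher with DPD in 25 of the 29 regions that lost Fur with rifampicin and in 24 of 29 without it, counts that carry no test.

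By limma 1379 bins were higher and 1403 lower, with 34 and 32 at 2-fold or more. Windows around the Fur regions rose at 20 and fell at 8 of 32, with a median of 0.40 on the log2 scale, and library totals gave the same counts. Among the 99 bins within 1 kb, 49 rose and 25 fell with a median of 0.11 (camera p = 0.000155, and p = 0.00609 with an estimated correlation of -0.0099). Of 34 bins that rose by 2-fold or more, 18 were near a Fur region, where chance gives 0.726 (permutation test by circular shifts, one-sided, p = 0.000647).

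**Figure D3:**
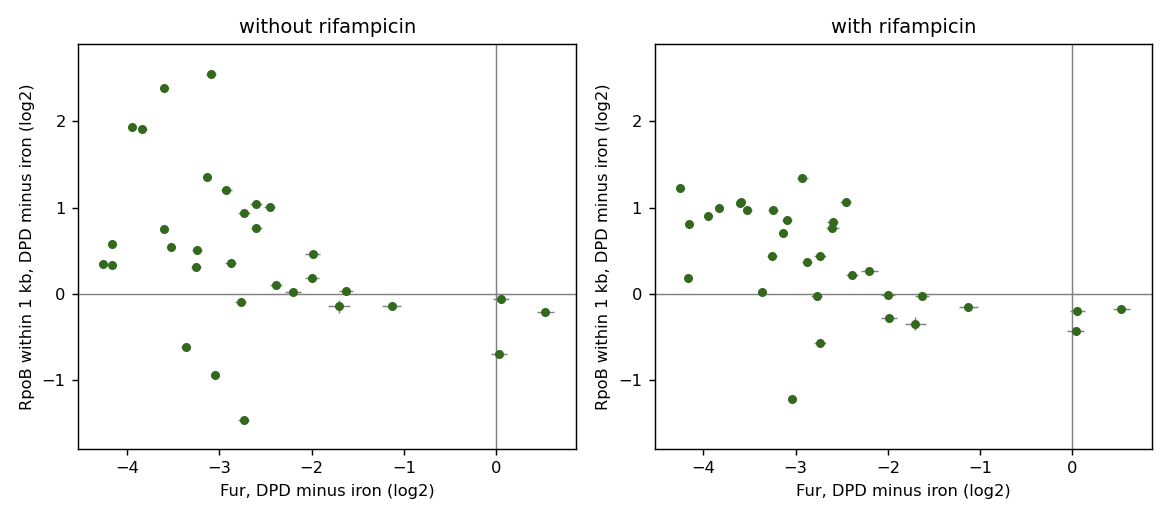
Change of Fur in each of the 32 regions (x axis, log2, DPD minus iron) against the change of RpoB within 1 kb (y axis, log2), without rifampicin on the left and with it on the right, with standard errors as bars. Points lie above 0 at most regions that lost Fur, with called rises at 21 and 20 of 29, and the largest values are 2.55 without and 1.34 with rifampicin.

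Iron effects with and without rifampicin, which share no libraries, ran partly in parallel. Both comparisons called 768 bins higher, against 493 for independent lists, and 739 lower, against 474. Another 567 bins were called in opposite directions. Although they share no libraries, the comparisons are not fully independent. Both came from the same fit and use its variances. Both also set DPD files with some shorter reads against iron files without them. How much of the overlap comes from these shared features was not tested. Across bins, which are not independent replicates, Pearson's r was 0.40 and Spearman's rho 0.37. The difference of both iron effects was itself called in 2926 bins by limma, higher with rifampicin in 1427 and lower in 1499. With library totals these counts were 649 and 2892.

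Rifampicin redistributed RNA polymerase along most of the genome. With iron, polymerase signal fell from 24.7 ± 0.392 to 0.425 ± 0.0084 at 780001 to 781000 (SD, n = 2). At 3423001 to 3424000 it fell from 39.7 ± 2.02 to 0.839 ± 0.0067. Neither end value was below the median bin signal, of which the pseudocount of 0.200 is 0.5. The 10 leading falls ran over 2 to 12 bins, including 228001 to 229000 in a run of 11 and 4209001 to 4210000 in a run of 12. The 10 leading rises ran over 1 to 5 bins. The signal went from 0.273 ± 0.036 to 10.2 ± 0.418 at 2797001 to 2798000, from 0.134 ± 0.029 to 3.65 ± 0.141 at 4460001 to 4461000 and from 0.497 ± 0.0017 to 6.14 ± 0.040 at 732001 to 733000. By limma 2126 bins were higher and 2014 lower with iron, 734 and 826 of them by 2-fold or more. Library totals, which shifted the median bin by 0.12, turned this balance to 901 higher and 680 lower by 2-fold or more. With a pseudocount of 0.1 of the median signal, 1024 rises and 1137 falls reached 2-fold.

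With DPD, rifampicin raised polymerase at bins that had also risen with iron. The signal went from 0.305 ± 0.0086 to 5.22 ± 0.052 at 2884001 to 2885000, from 0.709 ± 0.058 to 9.10 ± 0.027 at 732001 to 733000 and from 0.376 ± 0.069 to 4.40 ± 0.021 at 4460001 to 4461000. Falls were largest at 3949001 to 3950000, from 14.1 ± 0.410 to 0.0902 ± 0.00735, and at 81001 to 82000, from 7.15 ± 0.162 to 0.0583 ± 0.0093. The bin at 2799001 to 2800000, which had the largest log2 rise of the named bins with DPD, dropped from 5.64 ± 0.154 to 0.139 ± 5.9e-05 once rifampicin was added. Limma called 2096 bins higher and 2033 lower, 648 and 752 by 2-fold or more.

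Polymerase signal became more concentrated within bins. The share of a bin's signal in its highest 100-base tile, taken as the median over bins of each library, was 19.4% ± 0.090 with iron and 20.0% ± 0.022 with DPD (SD, n = 2). It was 29.95% ± 0.457 with iron and rifampicin and 31.7% ± 0.234 with DPD and rifampicin. Each of the 4 rifampicin libraries exceeded each of the other 4, by 11.1 percentage points on average (exact permutation test, two-sided, p = 0.0286, the smallest that 70 arrangements allow). Permuted within the replicate number, p was 0.0556, the smallest that 36 arrangements allow. With every bin thinned to 40 reads, the difference was 9.38 points. The measure was chosen after the files were examined, in place of a ratio of promoter to gene signal that needs gene positions.

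**Figure D4:**
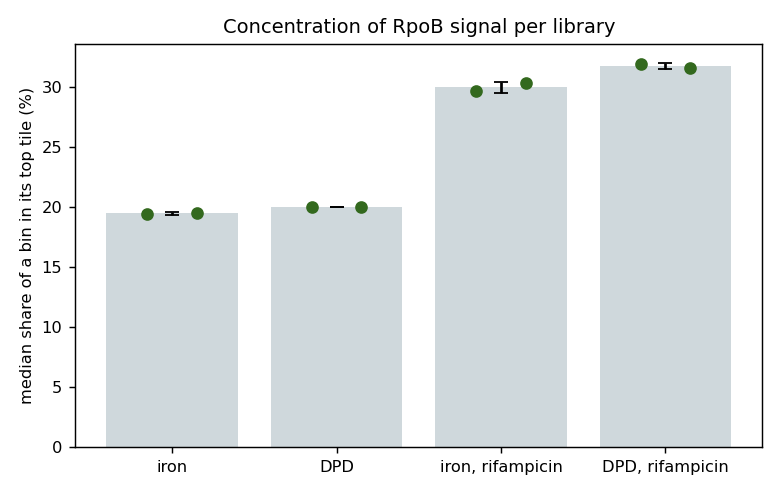
Median share of a 1 kb bin's RpoB signal that falls in its highest 100-base tile (y axis, percent) in each RpoB group, with 1 point per library, bars at the mean and error bars of 1 SD (n = 2). Rifampicin groups have means of 29.95 and 31.7, and groups without it have 19.4 and 20.0.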

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

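Of the tests in this part, the comparison of read lengths was chosen only after the result was seen, and the comparison of slopes was set out before it. The effect of iron withdrawal on RpoB differed with rifampicin, by a test of the difference itself: it was higher with rifampicin in 1427 bins and lower in 1499 of 4639 (limma, adjusted over the bins), 212 and 96 of them by 2-fold or more. With library totals, which shift the median bin by -0.23, the counts were 649 and 2892, with 134 and 193 at 2-fold or more, so the balance of large differences turned over.

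The largest positive difference of the named bins, on the log2 scale, was at 2040001 to 2041000. There polymerase was 7.21 ± 0.110 with iron against 0.473 ± 0.023 with DPD, but 1.28 ± 0.024 against 1.02 ± 0.012 once rifampicin was present (SD, n = 2). At 3426001 to 3427000 the signal of 78.8 ± 2.43 with iron and 21.9 ± 0.603 with DPD became 7.17 ± 0.308 and 9.15 ± 0.117. The largest negative difference was at 2799001 to 2800000, where a rise from 0.205 ± 0.017 to 5.64 ± 0.154 shrank to 0.0986 ± 0.00010 and 0.139 ± 5.9e-05. Next came 613001 to 614000, where 0.101 ± 0.0045 and 2.21 ± 0.042 became 0.0739 ± 0.0017 and 0.0727 ± 0.0040. Of the 10 leading negative differences 4 were within 1 kb of a Fur region, and of the positive ones 0.

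One explanation for the differing iron effect is that rifampicin lowers polymerase towards the background in transcribed stretches, where no iron effect can then be seen. The slope of the iron effect with rifampicin on that without was 0.0459 in 785 bins that rifampicin lowered by 2-fold or more, averaged over iron and DPD, and 0.630 in 676 that it raised. The difference of -0.584 had a 95% bootstrap interval of -0.669 to -0.499. The pseudocount of 0.200 shrinks log2 changes of low bins, so a lower slope in lowered bins was partly set by the scale. The comparison therefore cannot show how much of the pattern a loss of signal accounts for. Shorter reads in the DPD files are argued against as its cause, because their mean length differed by 0.0585% between DPD libraries without and with rifampicin. A regulation of starting and moving polymerase that differs with iron was not tested and stays open.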

How the results depend on the processing

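Tests chosen only after the data were seen were those with the pseudocount of 0.1 of the median, the 500-base bins and the share of the highest tile. Of 150 alternatives over 14 results, 133 kept direction and call or stayed within 1.5 times the count. The 133 include the tests without the low-signal filter, which repeat the main result by construction. Counts for 500-base bins were compared as raw numbers, although 9270 bins were tested there against 4639. With library totals, DPD against iron gave 3249 higher and 738 lower bins, and the difference with rifampicin gave 649 and 2892; totals rest on the few strongest tiles, which held more of the signal with iron than with DPD without rifampicin. Bins of 500 bases, 9270 in number, gave 2426 higher and 2928 lower with DPD, and 2186 higher and 2319 lower with rifampicin; the cause of the changed balance was not tested. A scale set on the Fur regions gave 13 higher and 12 lower, by construction. Regions at 10 times the median gave 0 higher and 23 lower of 23 (limma), those at 3 times 15 higher and 38 lower of 74, and those with at least 2 times the RpoB enrichment 16 lower of 17, which follows their number. Near regions at 3 times the median the RpoB change was 0.064 (p = 0.185 with the preset correlation), against 0.73 at 10 times; the cause was not tested.

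Leaving out each library in turn gave 0 to 2 higher and 29 to 30 lower Fur regions, 1453 to 1550 higher and 1453 to 1490 lower RpoB bins with DPD, and 10.8 to 11.5 points for the highest tile. A lone library of a group was assumed to vary like the others. The median Fur change ran from -1.96 to -3.63 with a pseudocount that follows the median signal, and was -3.86 with the smaller pseudocount. Libraries with the same number did not deviate together (correlations of -0.0494 to 0.0605), and the replicate block changed no count by over 1.5 times (1652 higher and 1563 lower with DPD). An exact permutation within the replicate number left the 11.1 points of the highest tile at p = 0.0556, the smallest that 36 arrangements allow. The test without a low-signal filter removed nothing and says nothing of stability. Alternatives on genes, promoters and known promoters were not run, for want of gene positions. The shallowest library, Fur with iron, held 687059 reads, and leaving it out gave 30 lower and 2 higher Fur regions.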

Other observations

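All tests in this part were chosen only after the results were seen. Rises of polymerase with DPD were more frequent and larger at and near the regions that lost Fur, although most rising bins lay elsewhere. In the 35 bins overlapping them, 26 rose and 6 fell, with a median log2 change of 1.07 without rifampicin and 0.97 with it. In bins up to 1000 bases away the medians were 0.20 and 0.03, and in the next up to 2000 bases they were 0.16 and 0.03. The following class, up to 5000 bases, still had 94 rises and 28 falls among 162 bins, with medians of 0.16 and 0.04. Beyond 10000 bases 1371 bins rose and 1434 fell, with a median of 0.00 without rifampicin.

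Some of the strongest read ends of the Fur libraries with DPD were nearly absent with iron, and others were present in both conditions. The highest was at 4173411 on the plus strand, with 307 and 209 reads against 1 and 0 with iron. The next was at 2056126 on the minus strand, with 264 and 158 reads against 0 and 0. These lie 74611 and 10175 bases from the nearest Fur region. A site at 3731514 on the minus strand had 165 and 131 reads with DPD and 107 and 30 with iron. In RPM, reads scaled to library size, these are 50.6 and 50.8 against 40.9 and 43.7, so this site was present in both conditions. A read end at 255804 on the plus strand, inside the Fur region at 255801 to 255900, was present in both as well. It had 24.8 and 26.4 RPM with DPD against 22.2 and 24.7 with iron. These positions were chosen for their values and carry no test.

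The near absence of Fur signal with DPD was weighed against technical causes. Lower depth is argued against, because the shallowest Fur library was an iron library. With 3.81 times fewer reads than the other iron library, it had 1.02 times its enrichment in the median of all 32 regions (range 0.723 to 1.19). A weaker or failed precipitation under chelation cannot be told apart from loss of binding: of 27 regions with at least 10 times the background with iron, 0 kept 50% or more of their excess. The 3 regions at 255801, 3580801 and 3595801, weak with iron, kept or gained signal. No untagged control was used here to show that this signal is Fur. These regions therefore leave both readings, and release of Fur as a possible explanation named by the design, open.

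The rise of RpoB around Fur regions was weighed likewise. Shorter reads in the DPD files act across the genome, and placing the same windows elsewhere 10000 times gave no median as high as the observed 0.49, here computed from tiles (permutation p = 0.0001, the smallest possible; highest 0.20). Bins of the same RpoB level gave at most 0.11 against 0.31 in 10000 random sets (permutation p = 0.0001, the smallest possible). This argues against signal level as the cause, with a limit. The random sets take bins as independent, whereas the bins near Fur regions are neighbours, so this p is likely too small. Over the 32 regions, a larger fall of Fur went with a larger rise of RpoB (Spearman's rho -0.487, permutation p = 0.00556, and -0.632, p = 0.00012 with rifampicin). Pearson's r was -0.430. Fur with DPD lay between 0.870 and 2.27 in all 29 regions that fell, so the size of a fall mostly follows the Fur level with iron. The correlation therefore cannot tell whether RpoB rose with the loss of Fur or only at sites where Fur was strong with iron. A weaker Fur precipitation could bear on the Fur change only, because RpoB was precipitated separately in wild-type cells. Release of polymerase by loss of Fur stays open. Within the 29 regions that fell, rho was -0.388 and -0.562, neighbouring regions are not independent, and falls such as that at 2066301 to 2066900 go against a uniform release.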
